A study of Mus musculus with 23 samples.

How the data were processed

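RNA was sequenced from mouse embryonic stem cells (ESCs) and from embryoid bodies (EBs), the aggregates that ESCs form in suspension when leukaemia inhibitory factor is withdrawn. The series holds 23 samples. The 10 RNA-seq libraries used here fall into 5 groups of 2: wild-type (WT) and Trim33-null EBs at day 2.5, each treated with activin A at 50 ng/ml or with SB431542, and ESCs of the line E14 treated with activin. The 8 ATAC-seq samples and the 5 ChIP-seq samples were not analysed here. Activin A is a ligand that signals through the receptors and SMAD proteins that Nodal uses, and SB431542 inhibits the kinase of the type I receptors. Activin was given for 2 h, and the labels list 15% serum for all 10 RNA-seq libraries. The dose of SB431542 is 10 micromolar in 1 part of the labels and 10 millimolar in another. The duration of SB431542 is 1 h in the protocol and 2 h in the sample titles. The titles of the ESC libraries carry the letters LKO, while their characteristics and table columns give wild type. The characteristics and table columns were followed, and the difference was not resolved. The EBs are described as having a C57BL/6J background, so cell state and cell line changed together in any comparison of EBs with E14 ESCs.

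The values used are FPKM (fragments scaled for gene length and library size) that the authors deposited in 1 table with a column per library. CASAVA 1.8, Bowtie2 2.2.2, STAR 2.4.0 and Cufflinks 2.2.1 and the build mm9 are named per the submitters' processing notes, which assign no role to each tool. The gene annotation, any filter on reads and the strandedness of the libraries are not given in the sources used here. All 10 columns of values were used. Column names give the group and a numeral, I or II. The numerals of the Trim33-null columns could not be matched to the numbers 1 and 4 in the sample titles, so libraries are named by column numeral. The table held 29145 entries. Where a symbol had several, the one with the highest mean FPKM was kept and 113 were left out, which left 29032 symbols.

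The table gives no read counts. The relative depth of the libraries was estimated from the steps between values under 0.06 FPKM, where a gene's values are whole multiples of what 1 fragment is worth, with a tolerance of 0.02 on the log2 scale. All pairs of libraries were solved jointly, and 6 of 6 runs reached the same score within 1 percent. Between 7.20% and 10.0% of low values fell on the step found. Tried as controls, a larger step held 3.24% to 6.09% and a smaller one 3.10% to 6.79%. These shares are low, so the depths are estimates, and no count test was run on them. Over the 10 libraries, relative depth and the number of genes listed at 0 had a Spearman correlation of -0.863.

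Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the empirical Bayes step, Benjamini-Hochberg (BH) adjustment over the genes tested and a threshold of 0.05. Adjusted p-values for genes come from this test, and fold changes with their standard errors (SE) are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 2 libraries of the fit were kept. The 8 EB libraries were fitted together, which gives 4 residual degrees of freedom, and all 10 libraries were fitted for the comparison of EBs with ESCs. A permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so calls rest on the spread shared across groups and genes. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

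Tested on simulated data, the fit found 86% of genes changed by 1 on the log2 scale and 97% of those changed by 2 in the comparison of activin with SB431542 in WT EBs, with 10 false calls among 193. For the genotype comparison under activin it found 84% and 96%, with 11 false calls among 191. For the difference in activin response between genotypes it found 80% and 87%, with 6 false calls among 173. For EBs against ESCs it found 88% and 99%, with 11 false calls among 198. In each simulation 100 genes were changed by each size, over 11317 genes in the EB fits and 11661 in the fit with ESCs. The simulated noise was independent between libraries. In the data, libraries of a column numeral deviated together across treatments (correlation across genes of 0.46 in WT and 0.91 in Trim33-null EBs). These rates therefore need not hold for the real comparisons.

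Before the data were examined, 25 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists covered Nodal/activin targets, primitive streak, definitive endoderm, mesoderm, naive and general pluripotency, formative epiblast, neuroectoderm, BMP and Wnt targets, Nodal pathway components, extraembryonic endoderm, trophoblast, fibroblasts, the 2-cell-like state, germline, p53 targets, immediate early genes, glycolysis, cell cycle, imprinted genes, sex-linked genes, chromosomal neighbours of Trim33, ribosomal proteins and mitochondrially encoded genes. Each list was tested with camera at a preset inter-gene correlation of 0.01, with BH adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For some lists the estimate lay below the preset value, so a call lost with it need not reflect correlation between genes. Of 150 tests over 6 comparisons, 57 passed at the preset correlation. The 2 that also passed with an estimated correlation were the Nodal/activin targets in the activin comparison of each genotype. The number of list members past the threshold is given over all genes tested and adjusted over the list alone. Because the lists were fixed beforehand, their members were not chosen from these values, but several genes stand in more than 1 list.

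Genes were named by rule. Among genes past the threshold whose libraries did not overlap between the groups and whose higher group had a mean of at least 5 FPKM, the 12 with the largest increase and the 12 with the largest decrease were taken, without gene models that lack a proper symbol. Where fewer than 5 passed, the genes with the smallest p were added up to 6. The 2 to 4 members of each list with the smallest p and any Nodal target could also be named. Some genes that the rule names are not reported here. Genes drawn in the plots per library were chosen after their values were seen. Chromosome membership and gene order came from a table of the assembly GRCm38.p6, matched by symbol for 4977 of the 5401 genes (92.1%) with a mean of at least 5 FPKM over the EB libraries, and no coordinates were taken from it. Medians of X-linked genes were set against 10000 random lists of autosomal genes matched on mean expression.

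The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, only the groups compared, a replicate block, an adjusted p threshold of 0.1 for overlaps, and leaving out each library in turn. Blocks by column numeral and the removal of both Trim33-null libraries of a numeral were added after seeing the data.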

Results

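The data are expression values of 10 mouse RNA-seq libraries in 5 groups of 2. EBs at day 2.5 were WT or Trim33-null and received activin A or the receptor inhibitor SB431542. ESCs of the line E14 received activin. Trim33 encodes a chromatin reader that binds activated SMAD proteins, and the series asks how Nodal signalling acts through it on mesendodermal genes. The summed FPKM per library ran from 236760 to 251652, and 10262 to 10846 genes reached 1 FPKM. Estimated relative depth, with the shallowest library at 1, was 4.41 and 3.07 for WT activin I and II, 2.62 and 1.45 for WT SB431542, 1.45 and 2.46 for Trim33-null activin, 3.23 and 2.85 for Trim33-null SB431542, and 1 and 1.27 for the ESCs. Pearson correlations across genes between libraries of a group were 0.995 for WT activin, 0.996 for WT SB431542, 0.984 for Trim33-null activin, 0.983 for Trim33-null SB431542 and 0.998 for ESCs. The first principal component held 61.3% of the variance and separated ESCs from EBs, and the second held 26.1% and separated the genotypes. The third, with 6.63%, separated column I from column II of the Trim33-null EBs, and the fourth, with 2.59%, separated activin from SB431542.

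Trim33 was measured first because it checks the genotype labels. In WT EBs it stood at 10.7 ± 0.93 FPKM under activin and 11 ± 0.061 under SB431542 (SD, n = 2). In Trim33-null EBs it stood at 2.46 ± 0.33 and 2.60 ± 0.33 FPKM, or 22.9% and 23.6% of WT. The change was -1.76 ± 0.10 (SE) on the log2 scale under activin (limma, adjusted p = 0.00279) and -1.74 ± 0.10 under SB431542 (adjusted p = 0.00304). The 4 Trim33-null libraries lay between 2.23 and 2.83 FPKM and the 4 WT libraries between 10.1 and 11.4. A value per gene does not show which exons the remaining fragments came from. E14 ESCs had 6.42 ± 0.25 FPKM.

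The comparison of activin with SB431542 in WT EBs asks which genes respond to the pathway. Lefty1, which encodes a secreted inhibitor of Nodal, rose from 9.18 ± 0.78 to 179 ± 3.4 FPKM, and Lefty2, its paralog, rose from 8.27 ± 1.1 to 40.2 ± 2.5 (SD, n = 2). Smad7, an inhibitory SMAD, rose from 1.33 ± 0.018 to 12.7 ± 1.3 FPKM. Gsc, a homeobox gene of the primitive streak organizer, rose from 0.192 ± 0.082 to 2.17 ± 0.77 FPKM. The log2 changes were 4.15 ± 0.11 (SE) for Lefty1, 2.54 ± 0.10 for Smad7, 2.15 ± 0.17 for Lefty2 and 1.39 ± 0.16 for Gsc, with limma adjusted p of 0.000127, 0.00079, 0.0113 and 0.0432. Outside the Nodal list, the Wnt receptor gene Fzd10 rose by 1.91, the Eph receptor gene Epha2 by 1.81 and the sulfotransferase gene Chst15 by 1.72. The transcription factor genes Irf1 and Hes1 rose by 1.71 and 1.49, the secreted kinase gene Pkdcc by 1.24 and Olig2 by 0.98. In total 25 of 11317 genes rose and 0 fell (limma with BH adjustment), and 299 genes had an unadjusted p under 0.05. That is fewer than a threshold of 0.05 gives when nothing changes, so this fit is conservative. With a replicate block within genotype by column numeral, whose meaning the labels do not give, 123 genes passed, 114 higher and 9 lower. The lower genes with the smallest p did not pass, among them Spry4, an inhibitor of receptor tyrosine kinase signalling, at -0.46 ± 0.09 (adjusted p = 0.357), Cited2 at -0.47 ± 0.10 (adjusted p = 0.467), Dusp4 at -0.27, Pnrc1 at -0.24, Larp7 at -0.53 and Lmo4 at -0.23. With any 1 of the 4 WT libraries left out, the count of 25 dropped to 4, or to 5 without WT SB431542 I.

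**Figure D1:**
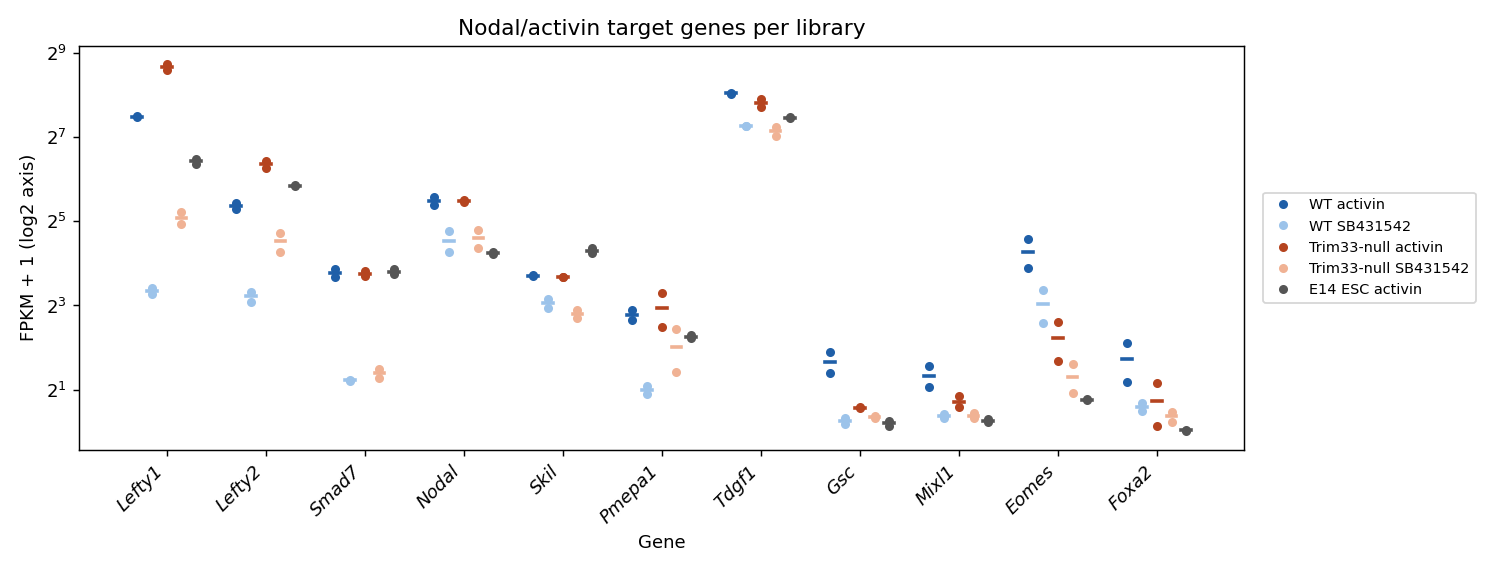
FPKM + 1 on a log2 axis for 11 Nodal/activin target genes, with a point per library, a bar at the mean of the 2 libraries of a group, and colours for the 5 groups. Lefty1 lay at 179 FPKM in WT EBs under activin and 9.18 under SB431542, and at 408 and 33 in Trim33-null EBs, while Gsc lay at 2.17 and 0.192 in WT and 0.484 and 0.274 in Trim33-null EBs.

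Of the 15 Nodal/activin targets measured in WT EBs, 5 rose over all genes tested and 12 when adjusted over the list alone. The list had a median log2 change of 1.07 and 14 of 15 members were positive (camera adjusted p = 1.75e-50, and adjusted p = 0.00209 with an estimated correlation). With a pseudocount of 0.1 the median was 1.87. Of 9 primitive streak and mesendoderm genes, Gsc rose over all genes tested and 7 genes when adjusted over the list alone, with a median of 1.07 (camera adjusted p = 2.14e-20, but adjusted p = 0.0725 with an estimated correlation). Wnt3, a ligand needed for streak formation, had 1.54 ± 0.22 (limma adjusted p = 0.0892) and Mixl1 0.93 ± 0.17 (adjusted p = 0.287). Msx1, a homeobox gene on the mesoderm and BMP lists, rose by 0.95 ± 0.10 (adjusted p = 0.0282). The mesoderm list had a median of 0.19 with 1 of 6 members risen and 2 adjusted over the list alone, the BMP targets 0.26 with 1 of 8 and 2, and the Wnt targets 0.22 with 0 of 8 and 0 (camera adjusted p = 2.21e-06, 2.21e-06 and 4.75e-06, but adjusted p = 0.0725, 0.143 and 0.143 with an estimated correlation). Definitive endoderm genes had a median of 0.29, naive genes 0.07, general pluripotency genes 0.08 and formative genes 0.07, with 0 members past the limma threshold (camera adjusted p = 0.00508, 0.00344, 0.000134 and 0.00224, but adjusted p = 0.143, 0.572, 0.572 and 0.575 with an estimated correlation). Their leading members were Nanog at 1.15 ± 0.20 (limma adjusted p = 0.223), Tdgf1, the Nodal co-receptor gene, at 0.78 ± 0.10 (adjusted p = 0.0668) and Fgf15 at 2.00 ± 0.26 (adjusted p = 0.0668). The other 16 lists did not pass, and their medians lay between -0.04 for immediate early genes and 0.05 for trophoblast and extraembryonic endoderm genes.

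The same comparison in Trim33-null EBs asks whether the response needs Trim33. Lefty1 rose from 33 ± 4.5 to 408 ± 26 FPKM and Lefty2 from 22.0 ± 5.1 to 80.9 ± 7.3 (SD, n = 2). Smad7 rose from 1.62 ± 0.27 to 12.5 ± 0.94 FPKM. Gsc had 0.274 ± 0.03 FPKM under SB431542 and 0.484 ± 0.014 under activin, a log2 difference of 0.22 that did not pass. The log2 changes were 3.59 ± 0.11 (SE) for Lefty1, 2.37 ± 0.10 for Smad7 and 1.85 ± 0.17 for Lefty2 (limma adjusted p = 0.000314, 0.00122 and 0.0237). Epha2 rose by 1.71, Fzd10 by 1.51, Irf1 by 1.40, Hes1 by 1.19, Pkdcc by 1.00, the adaptor gene Bcar3 by 0.86 and Olig2 by 0.84. In total 13 of 11317 genes rose and 0 fell (limma with BH adjustment), and 237 had an unadjusted p under 0.05. This is again fewer than a threshold of 0.05 gives when nothing changes. With the replicate block 83 genes passed, 78 higher and 5 lower. Spry4 at -0.54 ± 0.09 (adjusted p = 0.262), Trim13 at -0.33, Cited2 at -0.41, Zfand5 at -0.23, Net1 at -0.20 and Tbc1d23 at -0.20 were lower but did not pass. The count of 13 fell to between 4 and 8 with any 1 of the 8 EB libraries left out, lowest without Trim33-null SB431542 I and highest without Trim33-null activin I, and a fit to these 4 libraries alone gave 0 calls with 131 genes at an unadjusted p under 0.05 (limma). It gave 5 without both Trim33-null libraries of column II and 4 without both of column I.

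Of the 15 Nodal/activin targets measured in Trim33-null EBs, 4 rose over all genes tested and 7 when adjusted over the list alone, with a median of 0.87 and 15 of 15 members positive (camera adjusted p = 1.91e-45, and adjusted p = 0.00258 with an estimated correlation). With a pseudocount of 0.1 the median was 0.91. Primitive streak genes had a median of 0.61 with 0 of 9 past the limma threshold and 2 adjusted over the list alone (camera adjusted p = 1.55e-12, but adjusted p = 0.254 with an estimated correlation). Wnt3 had 1.31 ± 0.22 (limma adjusted p = 0.259) and Msx1 0.66 ± 0.10 (adjusted p = 0.168). Mesoderm, BMP and Wnt lists had medians of 0.09, 0.25 and 0.10 with 0 members past the limma threshold and 1, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0149, 0.000213 and 0.00291, but adjusted p = 0.369, 0.369 and 0.41 with an estimated correlation). The 2-cell-like genes, with a median of -0.27, and general pluripotency, glycolysis and ribosomal protein genes, with medians of 0.02, 0.09 and 0.04, passed camera. In these 4 lists 0 members passed limma, and 0, 1, 0 and 0 did so adjusted over the list alone (camera adjusted p = 0.0028, 0.0118, 0.0261 and 0.00172, but adjusted p = 0.719 for each with an estimated correlation).

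Set side by side, the 2 genotypes responded in a largely shared set of genes. Of 25 genes called in WT and 13 in Trim33-null EBs, 12 were called in both, where independent lists of those sizes would share 0.0287 (one-sided Fisher's exact test over 11317 genes, p = 7.37e-33). With the replicate block 76 were called in both, 73 higher and 3 lower. All 26 genes called in either genotype were positive in both, with median log2 changes of 0.99 in WT and 0.90 in Trim33-null EBs. The change was larger in WT for 24 of them, though genes selected mostly by their WT call are expected to favour WT. Ackr4, a chemokine scavenger receptor gene, was the single gene called in Trim33-null EBs alone (0.57 in WT and 1.22 in Trim33-null) and is named because it was the only one, after its values were seen. Across all genes tested, the changes in the 2 genotypes had a Pearson correlation of 0.772 and a Spearman correlation of 0.489. Genes are not independent replicates.

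**Figure D2:**
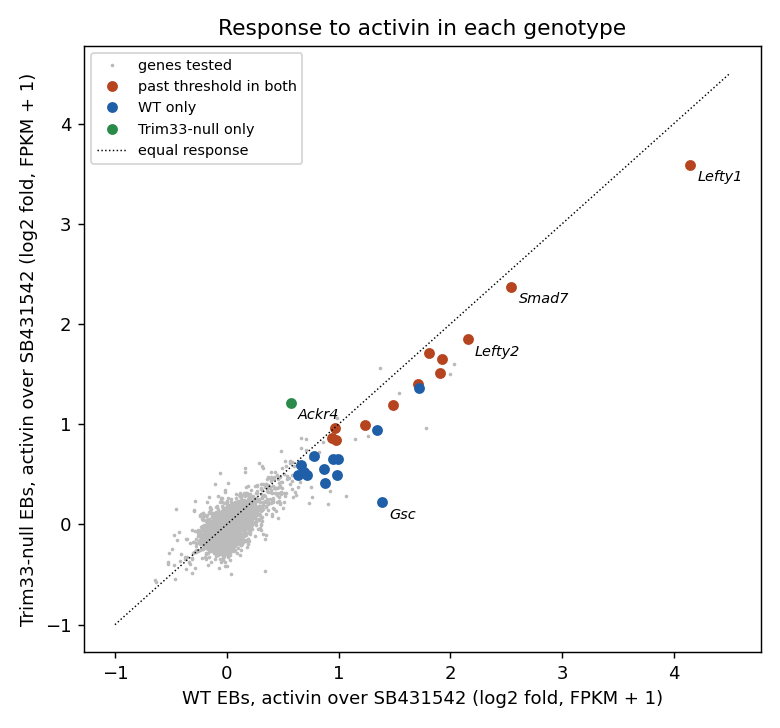
Log2 change from SB431542 to activin in WT EBs (horizontal axis) against that in Trim33-null EBs (vertical axis), with a point per gene and larger points for the 26 genes past the limma threshold in either genotype. All 26 are positive in both, 24 lie below the dotted line of equal response, and Gsc lies farthest below it among the labelled genes, at 1.39 in WT and 0.22 in Trim33-null EBs.

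The difference in response between the genotypes was then tested itself. No single gene passed: limma with BH adjustment called 0 of 11317 genes, and 24 had an unadjusted p under 0.05. That is far fewer than a threshold of 0.05 gives when nothing differs. Libraries of a column numeral deviated together across treatments, which this fit counts as error, so 0 calls do not show equal responses. With the replicate block limma also called 0 genes, and 277 had an unadjusted p under 0.05. Among genes whose higher group reached a mean of 5 FPKM, those with the smallest p in each direction are given, 5 of them with an unadjusted p above 0.05. The signed difference (the log2 change in Trim33-null EBs minus that in WT) was -0.70 ± 0.19 (SE) for Igfbp3, a binding protein of insulin-like growth factors, -0.56 ± 0.16 for Lefty1 and -0.40 ± 0.14 for Fzd10. It was -0.29 for Dact2, -0.31 for Klf5 and -0.21 for Dnmt3l. It was 0.32 for Klhl8, 0.27 for Rpl7a-ps8, 0.24 for Fxyd6, 0.19 for Mcat, 0.19 for Tgif1 and 0.15 for Krtcap3, and each of these 12 genes had an adjusted p of 1. The response of Gsc differed by -1.17 ± 0.23 and that of Mixl1 by -0.59 ± 0.25 (adjusted p = 1 for both). Adjusted over the list alone, Gsc was the 1 member to pass among the Nodal/activin targets (adjusted p = 0.0264) and among the primitive streak genes (adjusted p = 0.0159). Of the 15 Nodal/activin targets, 11 had a negative difference, with a median of -0.27. The list passed camera at the preset correlation (adjusted p = 6.17e-06) and not with an estimated one (adjusted p = 0.132 with an estimated correlation). The estimate was -0.034, below the preset 0.01, so a larger correlation is not what removed the call. Without the library WT activin II the median was -0.10 and the list no longer passed camera.

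The genotypes were next compared under activin, which asks what differs between Trim33-null and WT EBs when the pathway is stimulated. The Y-linked gene Eif2s3y stood at 9.65 FPKM in WT and 0.208 in Trim33-null EBs, so the lines may differ in more than Trim33. Effects of its loss, here and under SB431542, cannot be told apart from other differences between the lines. Dnmt3l, a DNA methylation cofactor, rose from 11.2 ± 0.043 to 31.1 ± 0.66 FPKM and Tex19.1, a germline gene, from 9.56 ± 0.21 to 30.4 ± 6.1. The naive genes Zfp42 and Tbx3 rose from 5.86 ± 0.89 to 13.6 ± 2.3 and from 1.08 ± 0.022 to 3.87 ± 0.47 (SD, n = 2). Eomes, a T-box gene of mesendoderm, fell from 18.5 ± 6.4 to 3.65 ± 2.0 FPKM, Otx2, a homeobox gene of the primed epiblast, from 18.9 ± 2.2 to 7.22 ± 2.0, and Gsc from 2.17 ± 0.77 to 0.484 ± 0.014. Lefty1 rose by 1.18 ± 0.11 and Lefty2 by 0.99 ± 0.17, against falls of -2.10 ± 0.44 for Eomes and -1.07 ± 0.16 for Gsc (SE, limma adjusted p = 0.00996, 0.0246, 0.0425 and 0.0185).

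The largest increases by the naming rule were in Ube2l6, a ubiquitin-like conjugating enzyme gene (2.83), Tcte2 (2.82), Prss35 (2.44), Fgfbp1 (2.13), Rpia, of the pentose phosphate pathway (2.07), Cyp2b23 (1.96), Tnfrsf22 (1.94), BC080695 (1.8), the water channel gene Aqp3 (1.69), Trap1a (1.65), Tex19.1 (1.56) and the tissue factor gene F3 (1.52). Ube2l6 rose from 9.96 ± 0.15 to 83.0 ± 45 FPKM and Prss35 from 1.40 ± 0.28 to 13.7 ± 9.7, so the Trim33-null libraries differed widely. The largest decreases were in the Y-linked genes Eif2s3y (-3.15) and Ddx3y (-2.46), Eomes (-2.10), Trim33 (-1.76), Ccrn4l (-1.61), Sgip1 (-1.54), the imprinted RNA Rian (-1.50), Fmo1 (-1.46), Slc38a6 (-1.44), Adamts13 (-1.35), the imprinted RNA Meg3 (-1.34) and Otx2 (-1.29). In total 915 of 11317 genes passed limma with BH adjustment, 385 higher and 530 lower, and 142 of them changed by at least 1 on the log2 scale (118 higher and 24 lower). This count depends on single libraries: it was 8 without WT activin I, 25 without WT activin II, 300 and 298 without WT SB431542 I and II, and 249 and 172 without Trim33-null activin I and II. A fit to the 4 activin libraries alone called 50 genes, and under median-of-ratios scaling 57.1% of calls were higher (430 against 323) where 42.1% were higher with the values as deposited. A replicate block by column numeral across genotypes, chosen after seeing the data, gave 2234 calls. The 8 EB libraries were fitted as independent, but Trim33-null libraries of a column numeral deviated together across treatments (correlation across genes of 0.91). The p-values behind the 915 calls may therefore be too small.

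**Figure D3:**
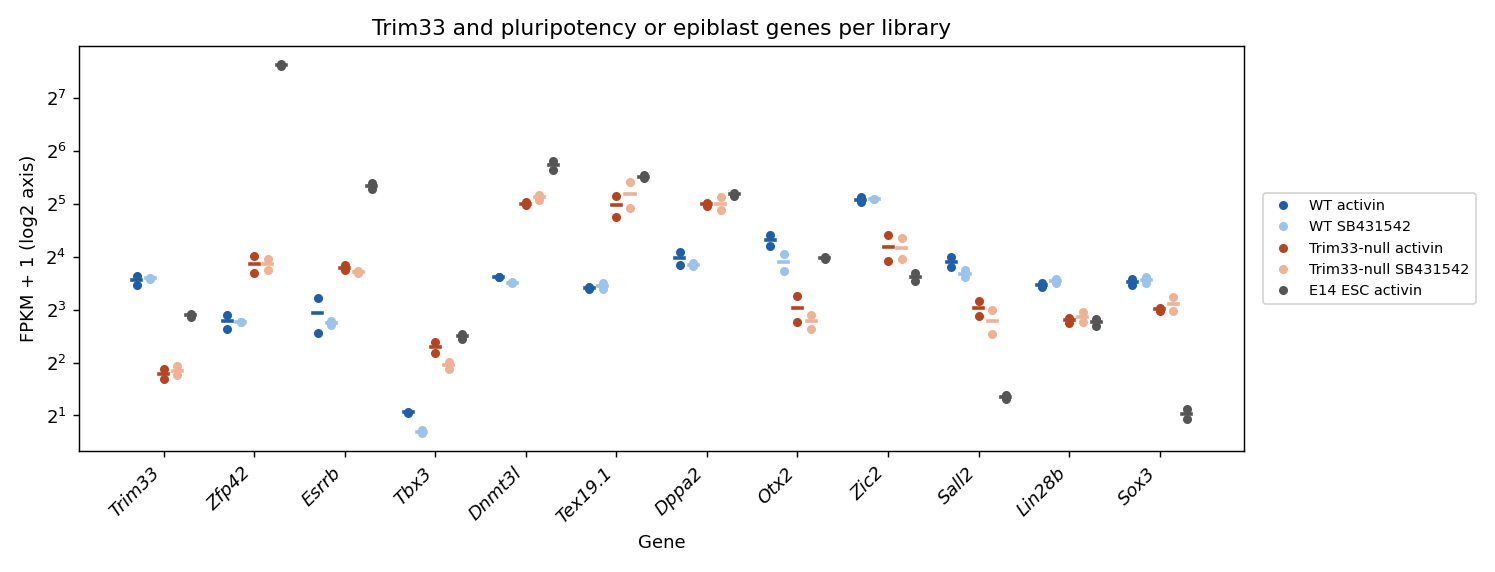
FPKM + 1 on a log2 axis for Trim33 and 11 pluripotency, germline, epiblast or neural genes, with a point per library, a bar at the mean of the 2 libraries of a group, and colours for the 5 groups. Trim33 lay at 2.46 and 2.60 FPKM in Trim33-null EBs against 10.7 and 11 in WT, Dnmt3l was higher in all 4 Trim33-null libraries than in the 4 WT ones, and Otx2 was lower.

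By list, 4 of 20 naive pluripotency genes rose in Trim33-null EBs under activin over all genes tested and 12 when adjusted over the list alone. The 4 were Tbx3 at 1.22 ± 0.09 (SE), Zfp42 at 1.08 ± 0.14, Esrrb at 0.90 ± 0.19 and Nr0b1 at 0.79 ± 0.13 (limma adjusted p = 0.00568, 0.0149, 0.0438 and 0.0242). The list median was 0.57 with 19 of 20 members positive (camera adjusted p = 2.78e-08, but adjusted p = 0.442 with an estimated correlation). The 2-cell-like list, markers of a rare state of ESC cultures, had 5 of 9 genes higher and 9 adjusted over the list alone, with a median of 1.06 (camera adjusted p = 9.01e-08, but adjusted p = 0.442 with an estimated correlation). Tdpoz4 rose by 0.99, Tcstv1 by 1.06 and Tcstv3 by 1.24 on the log2 scale, but reads may be shared between such near-identical genes, so single members are uncertain. Of 16 formative and primed epiblast genes 6 fell, 1 rose, and 10 and 1 did so when adjusted over the list alone, with a median of -0.66 (camera adjusted p = 0.027, but adjusted p = 0.542 with an estimated correlation). The gene that rose was Dnmt3l (1.40 ± 0.06), while Sox4 (-0.64 ± 0.06), Lin28b (-0.67 ± 0.08) and Otx2 fell. Of 7 neuroectoderm genes 3 fell and 4 did so adjusted over the list alone, among them Zic5 (-0.62 ± 0.10), Sox3 (-0.53 ± 0.10) and Zic2 (-0.91 ± 0.19), with a median of -0.43 (camera adjusted p = 0.0315, but adjusted p = 0.442 with an estimated correlation). Of 9 primitive streak genes Eomes and Gsc fell, and 4 did so adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.0315, but adjusted p = 0.542 with an estimated correlation). Fgf8 had -1.91 ± 0.54 (limma adjusted p = 0.08).

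Among markers of other cell types and signs of RNA quality, the fibroblast list had a median of 0.70 in Trim33-null EBs under activin with 0 of 13 members past the limma threshold and 0 adjusted over the list alone (camera adjusted p = 0.012, but adjusted p = 0.542 with an estimated correlation). The collagen genes Col6a1 and Col1a1 had 1.49 ± 0.67 and 1.20 ± 0.64 (SE, limma adjusted p = 0.202 and 0.269). Trophoblast genes had a median of 0.56, with Ascl2 higher (0.74 ± 0.08), Eomes lower, and 5 higher and 1 lower adjusted over the list alone. BMP targets had 0.45, with Bmp4 higher (0.43 ± 0.08) and 3 adjusted over the list alone. The p53 targets had 0.31, immediate early genes 0.16, cell cycle genes -0.17 with Aurkb lower (-0.38 ± 0.09) but 0 adjusted over the list alone, and mitochondrially encoded genes 0.17. The shifts of the fibroblast, p53, immediate early, cell cycle and mitochondrial lists were larger in column II of the Trim33-null EBs. Trophoblast genes had 0.61 in column I and 0.52 in column II, and BMP targets 0.33 and 0.39. The p53 targets had 0.02 in column I and 0.55 in column II, and immediate early genes 0.03 and 0.32. Cell cycle genes had -0.09 and -0.25, and mitochondrially encoded genes 0.10 and 0.36. For trophoblast, BMP, p53, immediate early, cell cycle and mitochondrial lists, camera adjusted p was 0.012, 0.0253, 0.0219, 0.0315, 0.012 and 0.012. With an estimated correlation the adjusted p was 0.442, 0.542, 0.542, 0.542, 0.542 and 0.542. All 3 Y-linked genes measured fell, Uty by -1.23 ± 0.07 beside Eif2s3y and Ddx3y, with 3 adjusted over the list alone and a median of -2.46 (camera adjusted p = 3.32e-05, but adjusted p = 0.442 with an estimated correlation). The Nodal targets, with a median of -0.04, did not pass, and 2 rose and 2 fell over all genes tested, 3 and 4 adjusted over the list alone. Pathway component genes had a median of -0.10 with 4 of 17 lower, Trim33 itself, the receptor genes Acvr1b (-0.32) and Acvr2b (-0.54) and the SMAD partner gene Foxh1 (-0.31). Lists that did not pass were definitive endoderm (-0.18), mesoderm (0.29), Wnt targets (-0.26), extraembryonic endoderm (0.47), germline (0.15), glycolysis (-0.07), imprinted genes (0.25), neighbours of Trim33 (-0.03), ribosomal proteins (-0.02) and general pluripotency (-0.14, where the mean was 0.08).

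Under SB431542, with the pathway inhibited, the genotypes differed in much the same way. Dnmt3l stood at 10.4 ± 0.17 FPKM in WT and 33.8 ± 1.5 in Trim33-null EBs, Tex19.1 at 9.88 ± 0.55 and 35.4 ± 8.6, Zfp42 at 5.77 ± 0.0013 and 13.5 ± 1.5, and Otx2 at 13.9 ± 2.4 and 5.86 ± 0.88 (SD, n = 2). Lefty1 rose from 9.18 ± 0.78 to 33 ± 4.5 FPKM and Lefty2 from 8.27 ± 1.1 to 22.0 ± 5.1, log2 changes of 1.74 ± 0.11 and 1.30 ± 0.17 (SE, limma adjusted p = 0.0042 and 0.0127). Eomes had 7.17 ± 3.1 FPKM in WT and 1.46 ± 0.8 in Trim33-null EBs, a difference of -1.72 ± 0.44 that did not pass (adjusted p = 0.0665). The genes named by rule that were not already named under activin were Plaur, a urokinase receptor gene (2.06), and Pramef25 (1.82) among the higher ones, and Car14, a carbonic anhydrase gene (-1.61), and Cpne8 (-1.27) among the lower ones. In total 914 genes passed limma with BH adjustment, 462 higher and 452 lower, and 182 changed by at least 1 on the log2 scale (157 higher and 25 lower). The count was 3 without WT SB431542 II, 14 without WT SB431542 I, 98 without Trim33-null SB431542 II, and 480 without either WT activin library. A fit to the 4 SB431542 libraries alone called 279 genes, and the replicate block across genotypes gave 2206. As under activin, libraries of a column numeral deviated together across treatments, so the p-values behind the 914 calls may be too small. The share of higher calls, 50.5%, was 60.4% under median-of-ratios scaling (517 against 339) and 40.6% under quantile normalization (412 against 604).

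Between treatments, 347 genes were higher in Trim33-null EBs in both comparisons, of 385 and 462, where independent lists would share 15.7. Likewise 380 were lower in both, of 530 and 452, against 21.2. Across genes, the genotype effects under the 2 treatments had a Pearson correlation of 0.975 and a Spearman correlation of 0.949, and no library is shared between these comparisons. Deviations of the Trim33-null libraries from their group means did go together across treatments, with a correlation across genes of 0.91 between activin and SB431542 libraries of a column numeral, so these effects are not independent measurements.

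Under SB431542, 6 of 20 naive genes rose and 15 did so when adjusted over the list alone, led by Tbx3 (1.25 ± 0.09), Nr0b1 (1.05 ± 0.13), Zfp42 (1.10 ± 0.14) and Klf5 (0.65 ± 0.09), with a median of 0.68 (camera adjusted p = 8.52e-09, but adjusted p = 0.272 with an estimated correlation). The 2-cell-like list had 6 of 9 higher and 9 adjusted over the list alone, with a median of 1.37 (camera adjusted p = 3.92e-08, but adjusted p = 0.328 with an estimated correlation). Of 16 formative genes 5 fell and Dnmt3l rose, 8 and 3 adjusted over the list alone, with a median of -0.65 (camera adjusted p = 0.0479, but adjusted p = 0.611 with an estimated correlation). Of 7 neuroectoderm genes Zic5, Zic2 and Sox3 fell, 4 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.0286, but adjusted p = 0.272 with an estimated correlation). Germline genes had a median of 0.19 with Tex19.1 (1.72), Dmrtb1 (0.65) and Mael (0.60) higher and 4 adjusted over the list alone (camera adjusted p = 0.0225, but adjusted p = 0.272 with an estimated correlation). Mesoderm genes had a median of 0.34 with Bmp4 (0.65) and Snai1 (0.75) higher and 2 adjusted over the list alone (camera adjusted p = 0.0286, but adjusted p = 0.272 with an estimated correlation). Beside these, fibroblast genes had a median of 0.90 with 0 of 13 past the limma threshold and 0 adjusted over the list alone, and trophoblast genes 0.70 with 3 of 7 higher (Ascl2, Peg10 and Plet1), or 5 higher and 1 lower adjusted over the list alone. BMP targets had 0.48 with Bmp4 higher and 3 adjusted over the list alone, p53 targets 0.33, immediate early genes 0.12, cell cycle genes -0.15 with Aurkb lower and 0 adjusted over the list alone, mitochondrial genes 0.24, and Y-linked genes -2.42 with 3 of 3 lower by either count. For these 8 lists camera adjusted p was 0.012, 0.00642, 0.0063, 0.0465, 0.0479, 0.009, 0.00535 and 2.13e-05. In the same order, adjusted p = 0.612, 0.272, 0.363, 0.639, 0.611, 0.611, 0.54 and 0.272 with an estimated correlation. By column of the Trim33-null EBs, p53 targets had 0.11 in column I and 0.46 in column II, and immediate early genes -0.03 and 0.50. The other 11 lists did not pass, among them the Nodal targets with a median of 0.07, primitive streak genes with -0.18, pathway components with -0.08, general pluripotency genes with -0.05, whose mean was 0.14, and definitive endoderm with -0.22, whose camera direction was up.

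The columns of the Trim33-null EBs differed in ways that the labels do not explain. The median of fibroblast genes relative to WT was 0.28 and 0.29 in column I (activin and SB431542) and 1.15 and 1.5 in column II. Col1a1 stood at 2.73 and 2.97 FPKM in column I and 8.98 and 10.3 in column II. Tagln and Acta2, contractile genes on that list, stood at 99% and 92.9% of WT under activin and at 97.8% and 86.1% under SB431542. The naive list had medians of 0.74 and 0.67 in column I and 0.44 and 0.66 in column II, and the 2-cell-like list 1.14 and 1.42 against 0.98 and 1.20. Primitive streak genes had -0.47 and -0.01 in column I and -0.84 and -0.34 in column II. Definitive endoderm genes had 0.12 and 0.11 against -0.63 and -0.34, and formative genes -0.60 and -0.43 against -0.70 and -0.71. X-linked genes also differed. Over 169 X-linked genes, the median difference from WT was 0 and 0.04 in column I and 0.32 and 0.30 in column II, where autosomal genes had medians of -0.04, -0.01, -0.06 and -0.06. In column I the 57 genes of the first part of the chromosome had medians of 0.39 and 0.39, and the next 56 and the last 56 had -0.04 and 0.01, and -0.10 and -0.06. With both Trim33-null libraries of a column left out, no Trim33-null replicate remains within a treatment. The spread then comes from WT libraries alone, so counts of genotype calls from such fits do not compare the columns.

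**Figure D4:**
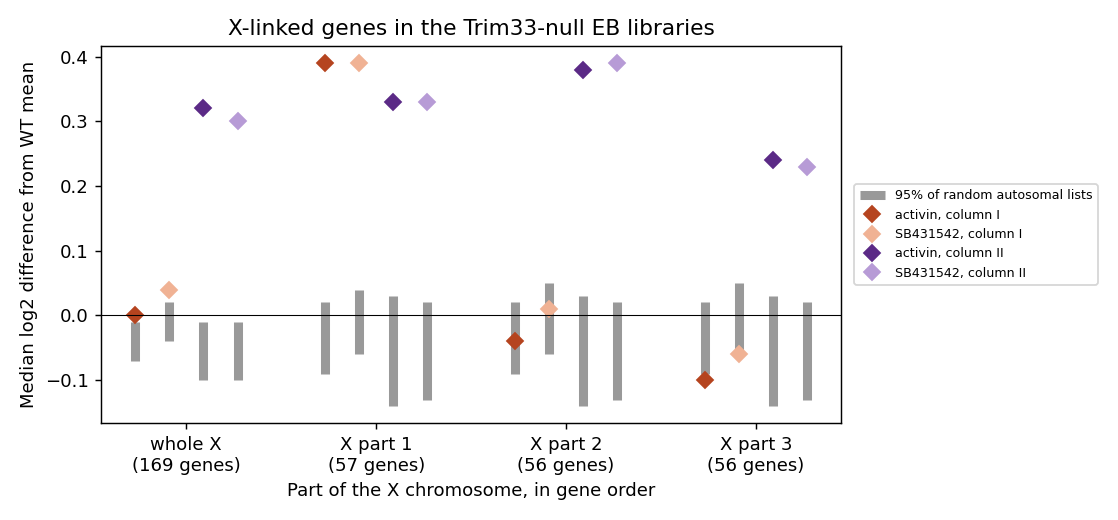
Median log2 difference from the WT mean of X-linked genes in each Trim33-null EB library (diamonds), for the whole X chromosome and for 3 parts in gene order, with grey bars for the middle 95% of 10000 random autosomal lists matched on expression. Column II lay at 0.32 and 0.30 over the whole chromosome, and in column I the first part lay at 0.39, the next part inside the grey bars, and the last part at -0.10 under activin, just below its bar, and at -0.06 under SB431542.

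WT EBs under activin were last compared with E14 ESCs under activin, which sets EB formation beside the starting state but also a different line. The titles of these ESC libraries carry the letters LKO, so their wild-type genotype rests on the characteristics and column names. Zfp42, a marker of naive ESCs, stood at 195 ± 3.9 FPKM in ESCs and 5.86 ± 0.89 in EBs, and Socs3, a target of leukaemia inhibitory factor signalling, at 20.7 ± 1.4 and 1.51 ± 0.054 (SD, n = 2). Fgf5, a marker of the primed epiblast, stood at 0.587 ± 0.071 FPKM in ESCs and 26.9 ± 1.5 in EBs, and Fgf8, expressed in the primitive streak, at 0.255 ± 0.09 and 23.1 ± 7.8. The log2 changes were -4.85 ± 0.13 (SE), -3.11 ± 0.13, 4.14 ± 0.32 and 4.23 ± 0.49 (limma adjusted p = 1.07e-06, 3.94e-06, 4.34e-05 and 0.000282). The largest increase was in Hprt, a purine salvage gene that is deleted in some E14 sublines, at 0.136 ± 0.018 FPKM in ESCs and 41.0 ± 3.1 in EBs (5.21 ± 0.29). Other increases were in Sos2 (4.05), the imprinted RNA H19 (3.91), Olig1 (3.81), Mgp (3.69), the activin antagonist gene Fst (3.64), the p53 target Pmaip1 (3.54) and Tmem254a, Tmem254b and Tmem254c (3.50, 3.52 and 3.52), which are near-identical copies and uncertain because reads may be shared. Decreases were in Laptm5 (-3.88), Triml2 (-3.48), Hsd17b14 (-3.23), Ccnb1ip1 (-3.21), Tgm1 (-3.14), Morc1 (-3.10), Fbxo15 (-3.06), Glrx (-3), Calml4 (-2.99) and Enox1 (-2.92). In total 6634 of 11661 genes passed limma with BH adjustment, 3557 higher in EBs and 3077 lower.

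Between ESCs and EBs, 18 of 20 naive genes fell, over all genes tested and adjusted over the list alone, with a median of -1.92 (camera adjusted p = 8.65e-09, but adjusted p = 0.6 with an estimated correlation). Of 9 primitive streak genes 8 rose by either count, among them Eomes (3.48 ± 0.40), Gsc (1.45 ± 0.15) and Wnt3 (1.67 ± 0.20), with a median of 1.62 (camera adjusted p = 0.00758, but adjusted p = 0.6 with an estimated correlation). General pluripotency genes had 7 of 12 lower and 1 higher by either count, with Sox2 at -0.89 ± 0.08 and a median of -0.42, and 2-cell-like genes 7 of 9 lower and 8 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 0.0391 and 0.0258, but adjusted p = 0.688 for both with an estimated correlation). Lists that did not pass camera still held many called genes. Of 16 formative genes 10 rose and 3 fell by either count, Fgf5 and Sall2 (2.56 ± 0.16) among those that rose and Dnmt3l (-2.11 ± 0.07) among those that fell, and of 7 neuroectoderm genes 5 rose and 1 fell by either count, with Sox3 at 2.5 ± 0.11. The Nodal targets had 8 of 15 higher and 3 lower by either count, with Lefty1 at 1.06 ± 0.11. The fibroblast list had 1 of 13 higher (Mgp) and 2 lower, 1 and 1 adjusted over the list alone, and 0 of 3 Y-linked genes passed limma.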

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

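The tests of gene lists were planned, and the tests given for single genes below are those of the planned comparison. What drew attention to each result is a difference in activin response between the genotypes, taken as Trim33-null minus WT. The Nodal/activin targets had a median difference of -0.27 (camera adjusted p = 6.17e-06, but adjusted p = 0.132 with an estimated correlation). For primitive streak genes it was -0.38 (camera adjusted p = 7.56e-05, but adjusted p = 0.534 with an estimated correlation), and for mesoderm genes -0.19 (camera adjusted p = 0.000748, but adjusted p = 0.217 with an estimated correlation). The 2-cell-like genes had -0.22 (camera adjusted p = 0.00151, but adjusted p = 0.641 with an estimated correlation) and germline genes -0.13 (camera adjusted p = 0.0421, but adjusted p = 0.525 with an estimated correlation). Glycolysis genes had 0.09, neighbours of Trim33 -0.06 and ribosomal protein genes 0.02 (camera adjusted p = 0.00492, 0.0491 and 0.00308, but adjusted p = 0.641 for each with an estimated correlation).

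Of 94 genes looked at, 4 had both libraries of 1 genotype moving with activin in one direction and both of the other genotype in the opposite direction. The differences were -0.21 for Dnmt3l, -0.31 for Klf5, 0.15 for Krtcap3 and 0.27 for Rpl7a-ps8. This way of finding them is not a test of the difference, which was not tested by it. All 4 were among the 94 because the naming rule took genes with a small interaction p. By chance, 2 libraries separate from 2 others in 33.3% of genes, so some opposite moves arise without a real difference. In limma with BH adjustment each had an adjusted p of 1.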

How the results depend on the processing

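The tests with a replicate block by column numeral and those without both Trim33-null libraries of a numeral were chosen only after the result was seen. Where a count moved, the cause was not tested, except that a filter at a mean of 5 FPKM tests fewer genes, that fits without a library or with only the groups compared hold fewer samples, and that a looser threshold calls more. Fewer samples do not by themselves explain a move, since activin calls in WT EBs rose from 25 to 38 with only the groups compared. A library left alone in its group is assumed to vary like the other groups.

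Genes called by activin in WT EBs (25) were 15 with no filter, 11 at a mean of 5 FPKM and 38 with only the groups compared, and 4 to 21 without 1 library (4 without WT activin I, WT activin II or WT SB431542 II, and 5 without WT SB431542 I). In Trim33-null EBs (13) they were 6 with no filter, 0 with only the groups compared (limma, 131 at unadjusted p under 0.05), 5 without both libraries of numeral II, 4 without both of numeral I, and 4 to 8 without 1 library. These were 5 without any 1 of the 4 WT libraries, Trim33-null activin II or SB431542 II, 4 without Trim33-null SB431542 I and 8 without Trim33-null activin I. The interaction had 0 calls in limma in all 18 alternatives, with 8 to 459 genes at unadjusted p under 0.05.

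Genotype calls under activin (915) were 315 at a mean of 5 FPKM, 50 with only the groups compared (40 higher, 10 lower) and 3355 without both Trim33-null libraries of numeral I. Without 1 library they ran from 8 to 956: 8 and 25 without WT activin I and II, 300 and 298 without WT SB431542 I and II, 249 and 172 without Trim33-null activin I and II. Under SB431542 (914) they were 293, 279 (191 higher, 88 lower) and 3380 in these settings. Without 1 library they ran from 3 to 935: 14 and 3 without WT SB431542 I and II, 480 and 480 without WT activin I and II, and 98 without Trim33-null SB431542 II. EBs against ESCs (6634) gave 2875 at a mean of 5 FPKM and 4610 to 6984 without 1 library.

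The labels do not say that a column numeral marks a shared culture or day. With a replicate block within genotype, activin calls were 123 in WT (114 higher, 9 lower) and 83 in Trim33-null EBs (78 higher, 5 lower), and the overlap was 76 (73 higher, 3 lower). A replicate block by column numeral gave 49 and 28 activin calls, and 2234 and 2206 genotype calls under activin and SB431542. As a random effect (consensus correlation 0.737) the block gave 864 and 847. Deviations of same-numbered libraries correlated across treatments at 0.46 in WT and 0.91 in Trim33-null EBs, and between genotypes at 0.21 to 0.44, a hint from the data and not the design. Gene list tests were not run with the block.

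The Nodal target median in WT (1.07) was 1.87 with a pseudocount of 0.1, 1.06 with median-of-ratios scaling, 0.96 with quantile normalization and 0.88 to 1.54 without 1 library. In Trim33-null EBs (0.87) it was 0.91 with a pseudocount of 0.1 and 0.60 to 0.88 without 1 library. Their difference (-0.27) ran from -0.31 to -0.09 and lost its call at -0.10 without WT activin II. List tests past the threshold (57) were 2 with an estimated correlation and 36 with fry. Of those with fry, 7 and 10 were in the genotype comparisons under activin and SB431542. At adjusted p under 0.1, overlaps were 20 (12) for activin and 1558 (727) for genotype. Of named genes called, 631 values in planned settings kept direction and call, 99 kept direction and lost the call, and 0 reversed. Without 1 library, 64.1% of such values kept both and 35.9% kept direction but lost the call. Genes listed at 0 ranged with depth from 5810 to 8540 per library, which limits genes of low expression.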

Other observations

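In this part the tests were chosen only after the result was seen, apart from those of single genes in the planned comparisons and that of a larger dose of the whole X chromosome. Of 17 imprinted genes, 3 were lower in Trim33-null EBs under activin, and all 3 are noncoding RNAs of the Dlk1-Dio3 cluster that are expressed from the maternal chromosome. Rian stood at 12.8 ± 3.7 FPKM in WT and 3.80 ± 0.69 in Trim33-null EBs, Meg3 at 7.25 ± 1.9 and 2.21 ± 0.36, and Mirg at 1.88 ± 0.44 and 0.64 ± 0.16 (SD, n = 2). The log2 changes were -1.50 ± 0.26 (SE), -1.34 ± 0.26 and -0.81 ± 0.18 under activin, and -1.52 ± 0.26, -1.44 ± 0.26 and -0.86 ± 0.18 under SB431542 (limma adjusted p = 0.0271, 0.0351 and 0.0486, then 0.025, 0.0287 and 0.0417). In E14 ESCs Rian stood at 12.7 ± 0.12, Meg3 at 4.25 ± 0.25 and Mirg at 1.63 ± 0.16 FPKM. The list as a whole did not pass camera, and 11 of its 17 members were positive in each treatment, with medians of 0.25 under activin and 0.41 under SB431542, where Peg10 rose by 0.93.

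Fibroblast genes were higher in the Trim33-null libraries of column II than in those of column I, by a median log2 ratio of FPKM, with no pseudocount, of 1.47 under activin and 1.8 under SB431542. Carry-over of male fibroblasts predicts that Y-linked genes rise by as much, and their medians were 1.66 and 1.70, at most 0.19 apart from the fibroblast genes, whose SD over members was 0.55 under activin. Such carry-over may account for this pattern, but the medians rest on 3 Y-linked genes. Of these, Uty did not rise under activin (0.133 FPKM in column I and 0.119 in column II). Tagln and Acta2, on the fibroblast list, did not exceed WT in the mean of both columns. Fibroblast genes in column I lay only 0.28 and 0.29 above WT by list median. Part of their level need not be carry-over, so the similar rise does not decide the question. Mesenchymal differentiation of cells that lack Y-linked transcripts predicts no rise of Y-linked genes, against 1.66, but these genes lie under 1 FPKM there, so it stays open.

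X-linked genes were higher in column II (medians of 0.323 and 0.305), where chromosome 12, at 0.106 and 0.134 against -0.056 and -0.018 in column I, and chromosome 6, at 0.089 and 0.108 against 0.057 and 0.105, had the highest medians of the autosomes. Scaling of the whole library is argued against, since the X-linked median exceeded the autosomal one by at least 0.36. A larger dose of the whole X chromosome in column II than in WT predicts a rise over WT in each of 3 parts of the chromosome, and the lowest value over parts and column II libraries was 0.29, which is consistent with it. The first part was as high over autosomes in column I (0.43 and 0.39) as in column II (0.39 and 0.38), so column II exceeded column I in the other 2 parts. No biological explanation other than X dose was tested.

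The naive list was higher in Trim33-null EBs by camera at the preset correlation and by fry (fry adjusted p = 0.0244 under activin and 0.0102 under SB431542). It did not pass camera with an estimated correlation (camera adjusted p = 0.442 under activin and 0.272 under SB431542). For this rise, 2 explanations are argued against. If carried-over fibroblasts were the whole cause, the naive excess over WT would grow from column I to column II as the fibroblast excess did. The fibroblast excess grew 6.31 times under activin and 7.46 times under SB431542 (medians over the 11 of 13 genes that exceeded WT in column I). Naive genes in column II lay below that level by a median of 1.76 (SD over 20 genes 0.61) and 1.99 (SD 0.96) on the log2 scale. The X-linked shift that column II has beyond column I would leave column I at the WT level, and the lower naive median there was 0.67. The shift of the first part of X, at least 0.38 in all 4 Trim33-null libraries, stays open, as does another difference between the lines, since 3 Y-linked genes were called in both treatments, and neither can be told apart from the loss of Trim33 because every Trim33-null library carries both.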
